A study of Mus musculus with 14 samples.

How the data were processed

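Retinal veins were dissected from 9-month-old mice under fluorescence, 5 minutes after an injection of sodium fluorescein at 0.33 mg per g of body weight, per the series design text. About 100 pg of RNA with an integrity number above 9 was reverse transcribed and amplified with SMART-Seq v4, a full-length method for very low input, and made into Nextera XT libraries for the Aviti sequencer, per the same text. It names kallisto with GRCm38 and GENCODE M23, whereas the submitters' processing notes list kallisto, sleuth and GRCm39, so the build behind the counts is not settled here. The deposited table holds signal values per gene symbol, which from the values are kallisto estimated counts divided by a size factor per library. How the factors were made and how transcripts were summed to genes is not given in the sources used here. With a tolerance of 0.01, between 19.1% and 22.2% of values in a library came out as whole reads, so whole reads were not recovered, although estimated counts need not be whole. No count model was run. Voom weights on reads estimated from the steps between low values were run as an alternative. That fit scaled each library to its own total in place of the deposited factors. The design had named a count test for estimated counts and limma for normalized values, and the second applied.

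Of 40149 rows, 26 with symbols turned into dates were left out, which held at most 0.201% of a library's total. Of the 40123 symbols left, 39019 matched GENCODE M21 (GRCm38), which gave coordinates, type, transcript length and GC content. Groups came from the sample labels. Genes at 1 or more in at least 5 libraries were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1), with group as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2(value + 1) scale. It shrinks changes of low genes, while a library at 0 can enlarge the change of other genes. The 42 gene lists were fixed before the data were examined, as were the test and the rule for named genes. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move one way and does not compare them with other genes. A count "adjusted over the list alone" adjusts the limma p-values within the list.

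Named genes were Gpnmb, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM, up to 4 members of each list past the threshold with the lowest p (or up to 2 not passing), and Cldn5, Cdh5, Mfsd2a, Plvap, Vwf, Nr2f2, Icam1, Vcam1 and Pecam1. Predicted genes, pseudogenes and sex-linked genes were kept out of the largest changes. Some genes that the rule names are not reported here. Hspb1, named as the 1 heat shock gene that fell, lies outside the rule and was chosen after its value was seen. Shares and length slopes were compared with exact permutation tests (n = 5 and n = 9). Relations across the 9 DBA/2J libraries were tested by exact permutation and adjusted over 9 relations with the activation mean and, added after the results were seen, over 3 with library number.

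In simulated data with these group sizes (28522 genes tested), 200 genes were changed, all with a mean of at least 5 CPM and a known transcript length. Of these, 60% of 2-fold and 94% of 4-fold genes were recovered, and 3.75% of calls were unchanged genes. Genes were drawn independently, without shared lens or library effects, and recovery at lower levels was not measured. With a simulated length slope of 0.3 between the groups, 81.7% of calls were unchanged genes as deposited and 4.76% after the length and GC correction, a spline of 5 degrees of freedom per library. That slope was linear in log2 length, a form the spline can remove, so other shapes of trend were not tested. The alternatives covered scaling, filters, pseudocounts of 0.1 and 5, weights, covariates, library subsets and each library left out. Reads from overlapping genes on opposite strands cannot be told apart where counting ignores strand, and near-identical copies such as crystallins, globins, Hspa1b and histocompatibility genes are uncertain. No pair of libraries agreed within sampling noise. Reads carry no molecular identifiers, so depth speaks for counting error only.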

Results

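Retinal veins of 9-month-old mice were profiled by RNA sequencing in DBA/2J, an inbred strain that develops high intraocular pressure and glaucoma with age, and in DBA/2J-Gpnmb+/SjJ, a related strain that carries a working Gpnmb allele and keeps normal pressure. The series title places the comparison in the question of how raised pressure affects the barrier between blood and retina and the loss of retinal ganglion cells. The 14 libraries comprised 9 from DBA/2J and 5 from the control strain, each made from 4 veins of 1 mouse, so p-values measure the spread between mice. Scaled totals ran from 14836190 to 22193399 per library. The depth estimated from the steps between low values ran from 8949499 to 33851455 reads, with DBA/2J samples 1 and 4 the shallowest at 8949499 and 10551534. Library numbers ran from 16 to 30 in the control group and from 31 to 39 in DBA/2J, so the order of library making and the strain cannot be told apart.

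Gpnmb, the melanosomal glycoprotein gene that differs between the strains by design, fell by 3.56 on the log2 scale in DBA/2J (SE 0.38, adjusted p = 4.35e-05, limma). Its scaled count was 1946 ± 712 (SD, n = 5) in control veins and 191 ± 140 (SD, n = 9) in DBA/2J veins. Control values lay between 1409 and 3190 and DBA/2J values between 65.4 and 516, so the groups did not overlap and every library matched its label. The gene (ENSMUSG00000029816.10) lies on the forward strand of chromosome 6, from 49036546 to 49070929 in GRCm38. The difference was -2.797 with the mean of the lens list as a covariate and then missed the threshold (adjusted p = 0.122, SE 0.579).

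**Figure D1:**
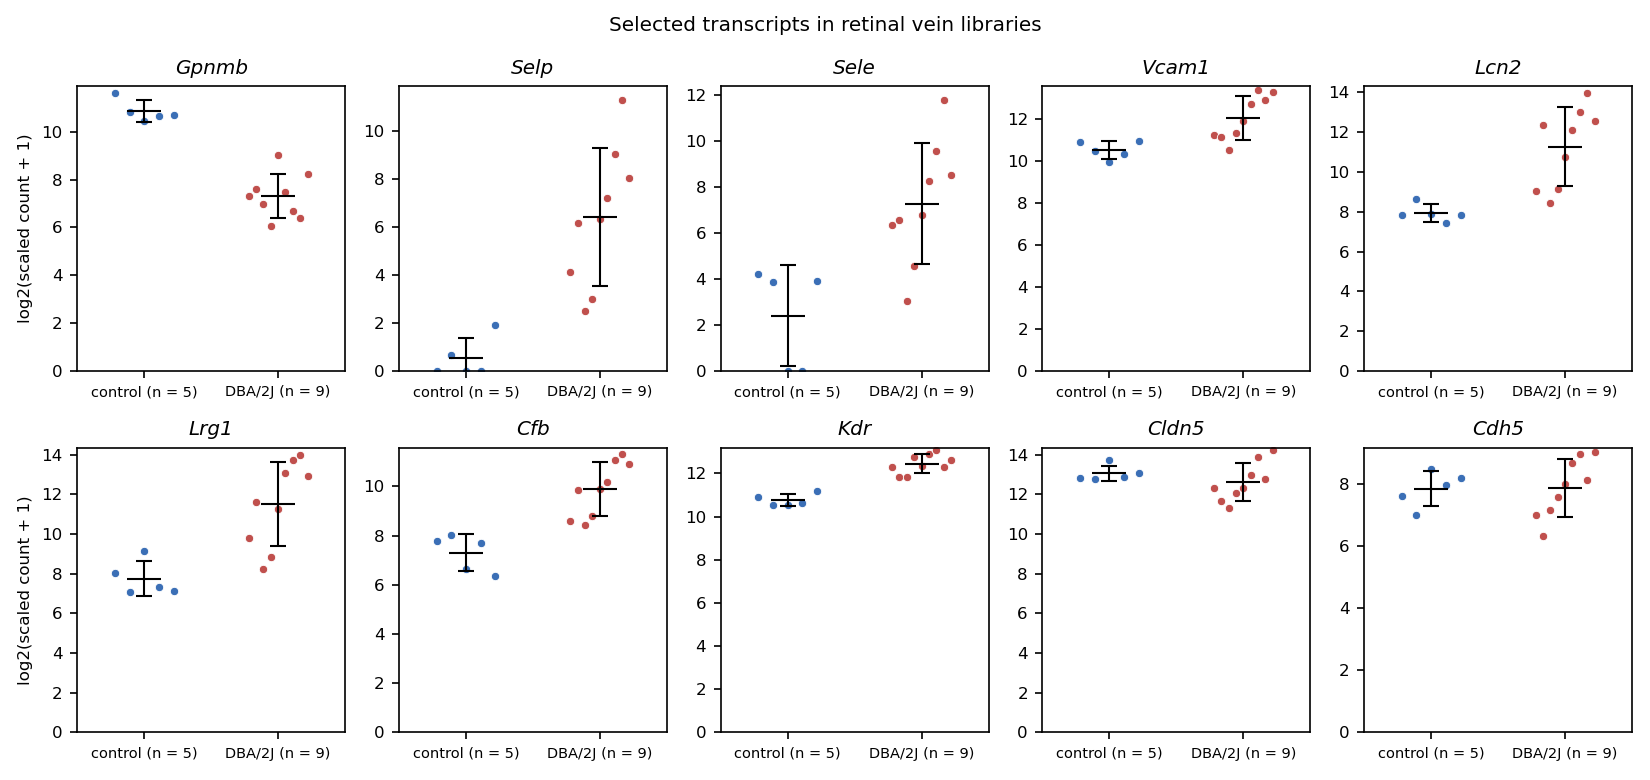
Each point is 1 library, the horizontal bar is the group mean and the error bar is 1 SD, on the log2(scaled count + 1) axis, for control (n = 5) and DBA/2J (n = 9). Gpnmb is lower in DBA/2J, and Selp, Sele, Vcam1, Lcn2, Lrg1, Cfb and Kdr are higher on average. Among the higher genes, Sele, Vcam1, Lcn2 and Lrg1 overlap in part between the groups, as do Cldn5 and Cdh5, which did not pass.

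Transcripts of the selectins Selp and Sele were higher and those of lens crystallins far lower in DBA/2J veins than in control veins. Of 29166 genes tested, 3518 were higher and 2101 lower in DBA/2J at an adjusted p under 0.05 (limma), of which 1500 and 992 differed by over 2-fold on the log2(value + 1) scale. Among the largest rises were those of Selp, Sele, C5ar1 (the C5a receptor), Lrg1 (an acute-phase glycoprotein), Ccr2 (a monocyte chemokine receptor), Kcna3, Lcn2 (lipocalin 2), Ly75, Ccl21a, Sash3 and Sla, with log2 fold changes from 5.89 for Selp to 3.07 for Sla. Kcna3 was at 0 in control sample 3, and Sash3 and Sla in control sample 5, which enlarges their log2 fold changes. For Kcna3 it was 3.35, with scaled counts of 96.1 ± 98.4 (SD, n = 5) in control and 399 ± 67.9 (SD, n = 9) in DBA/2J. Selp and Sele also had control libraries at 0. Lrg1 stood at 253 ± 183 (SD, n = 5) and 6000 ± 6011 (SD, n = 9), and Lcn2 at 253 ± 85.2 and 4856 ± 5154. The first principal component took 28.9% of the variance and held the controls at -69.8 to -39.4 and the DBA/2J libraries at 2 to 53. Higher genes made up 62.6% of those past the threshold as deposited. They made up 46.6% after a trend on transcript length and GC content was removed from each library (1859 higher, 2132 lower). Quantile normalization gave 2740 higher and 2868 lower. Voom weights, with each library scaled to its own total, gave 5213 and 1338. Without control sample 3, the counts were 2283 higher and 1247 lower, with controls 4 and 5 alone 1673 and 773, and with the mean of the lens list as a covariate 2 and 10.

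All 8 members of the lens list, crystallin genes, fell in DBA/2J (median log2 fold change -7.09, adjusted p = 6.21e-08, limma camera with a preset correlation; adjusted p = 0.76 with an estimated correlation). Adjusted over the list alone, 8 were also lower. Cryaa (chromosome 17, 31677807 to 31681733), the alpha-A crystallin, stood at 775000 ± 269700 (SD, n = 5) in control and 20160 ± 24930 (SD, n = 9) in DBA/2J. The lens list took 10.4% ± 3.74 (SD, n = 5) of the scaled counts of control libraries, between 6.88% and 14.9%. In DBA/2J it took 0.325% ± 0.395 (SD, n = 9), up to 0.976% (two-sided exact permutation p = 5e-04, the smallest these groups allow; adjusted p = 0.0015 over 6 shares). Rod markers took 4.49% ± 1.1 and 5.26% ± 1.62 (exact permutation p = 0.374), and pan-endothelial markers 0.153% ± 0.0283 and 0.257% ± 0.123 (exact permutation p = 0.0839). Crystallins are close relatives, so the split of reads among them is uncertain, and DBA/2J values spanned from 13.7 to 63520 for Cryaa.

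**Figure D2:**
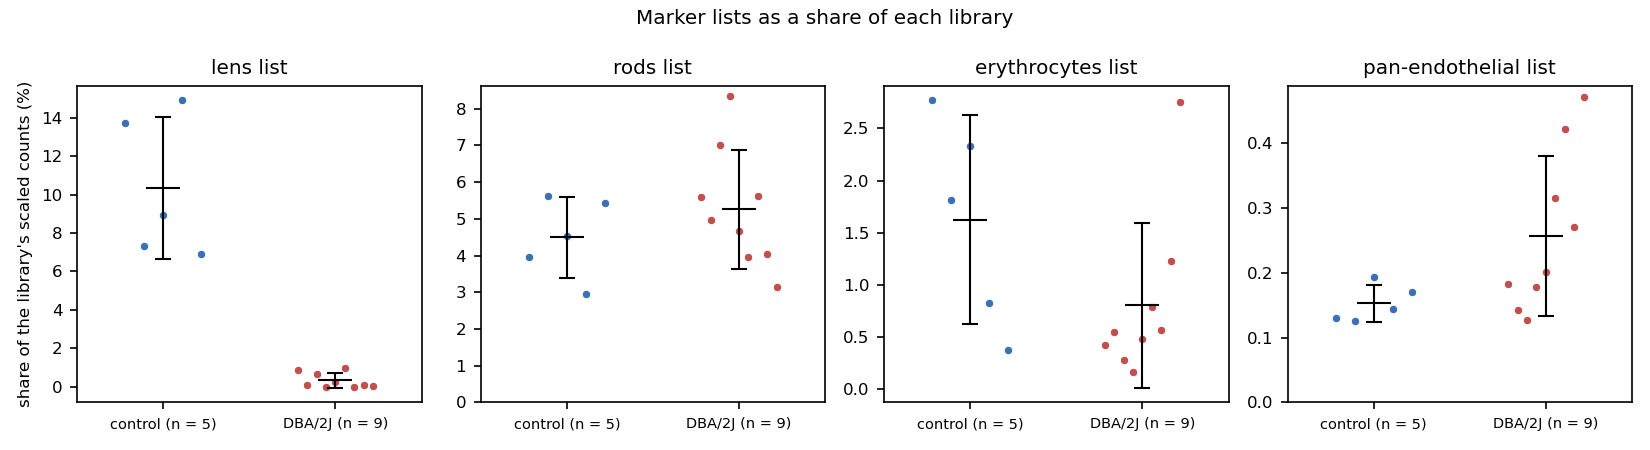
Each point is the share of 1 library's scaled counts (%) taken by a marker list, for control (n = 5) and DBA/2J (n = 9), with the mean and 1 SD. The lens list lies between 6.88% and 14.9% in control and at or under 0.976% in DBA/2J, and the other 3 lists overlap.

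Fold changes followed transcript length. In the shortest of 10 equal bins of coding genes (204 to 1455 nucleotides) the median log2 fold change was -0.474 and 43.2% of genes were lower in DBA/2J, against 1.06% higher. In bin 9 (5399 to 6947 nucleotides) the median was 0.537 and 43.8% were higher. For a slope per library, each gene's log2 values were first centred on its mean over all libraries. The slope of this centred value on log2 length was -0.213 ± 0.123 (SD, n = 5) in control libraries and 0.119 ± 0.11 (SD, n = 9) in DBA/2J (two-sided exact permutation p = 5e-04). Such slopes compare libraries with each other, so their opposite signs follow from the centring and only the difference between groups is informative. For each list called in the paragraphs on gene groups, the median and camera's adjusted p after removal of this trend are given as well. For the lens list they were -6.44 and 6.28e-08.

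**Figure D3:**
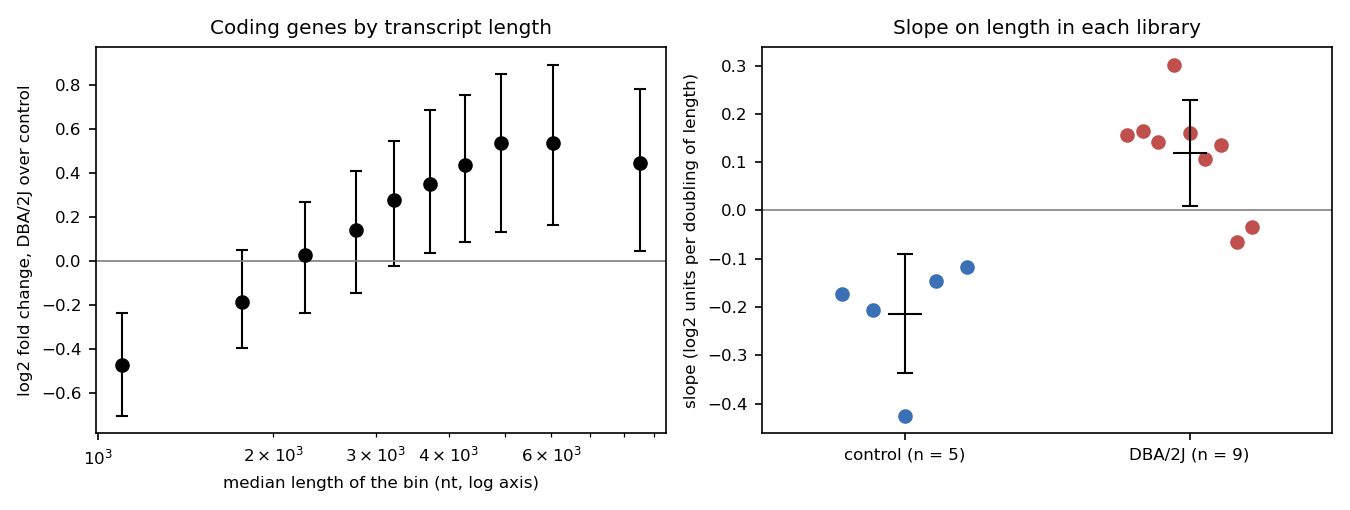
Left, the median log2 fold change (points) and quartiles (bars) of coding genes in 10 bins of transcript length, on a log axis in nucleotides. Right, the slope of log2 value on log2 length per library, with mean and 1 SD, for control (n = 5, -0.425 to -0.117) and DBA/2J (n = 9, -0.0658 to 0.302). Values were centred per gene on the mean over all libraries, so the slopes are relative.

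By camera with a preset correlation, 16 of 42 fixed gene lists were higher in DBA/2J and 4 lower. None passed with an estimated correlation (1 at an unadjusted p under 0.05), and 3 passed with fry (lens, endothelial activation and arterial endothelium; 13 unadjusted). Camera compared each list with all other genes tested, coding or not. Of 14889 coding genes with a mean of at least 1 CPM, 3107 were higher and 1308 lower (median log2 fold change 0.188). For lincRNA genes the median was -0.308. The counts of members given for each list are to be read against those of coding genes. Lists higher numbered 5 without control sample 4, 10 without control sample 2 and 8 without DBA/2J sample 9. They numbered 2 with a stricter filter on low values, where the median log2 fold change of all genes was 0.16 against 0.047. With replicate number as a block, Xist as a covariate or controls 1 to 3 alone the higher lists numbered 5 each. The block takes DBA/2J samples 6 to 9 out of the contrast, since no control has those numbers. With the pan-endothelial mean as a covariate 5 of the higher lists still passed: endothelial activation (median 1.33, adjusted p = 1.95e-05), complement (0.663, adjusted p = 0.00426), venous endothelium (0.672, adjusted p = 0.0112), VEGF and angiopoietin (0.357, adjusted p = 0.0124) and immediate early genes (0.444, adjusted p = 0.0185). The other 11 did not. They had adjusted p from 0.0817 (heat shock) to 0.887 (the pan-endothelial list, tested with its own mean). Of the 4 lower lists the retinal ganglion cell call was lost. With the leukocyte mean as a covariate 2 higher lists passed (endothelial activation and complement). With the Muller glia mean the number was 2 (endothelial activation and immediate early genes) and with the lens mean 4 (those 3 and venous endothelium), where none of the 4 lower lists still passed.

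**Figure D4:**
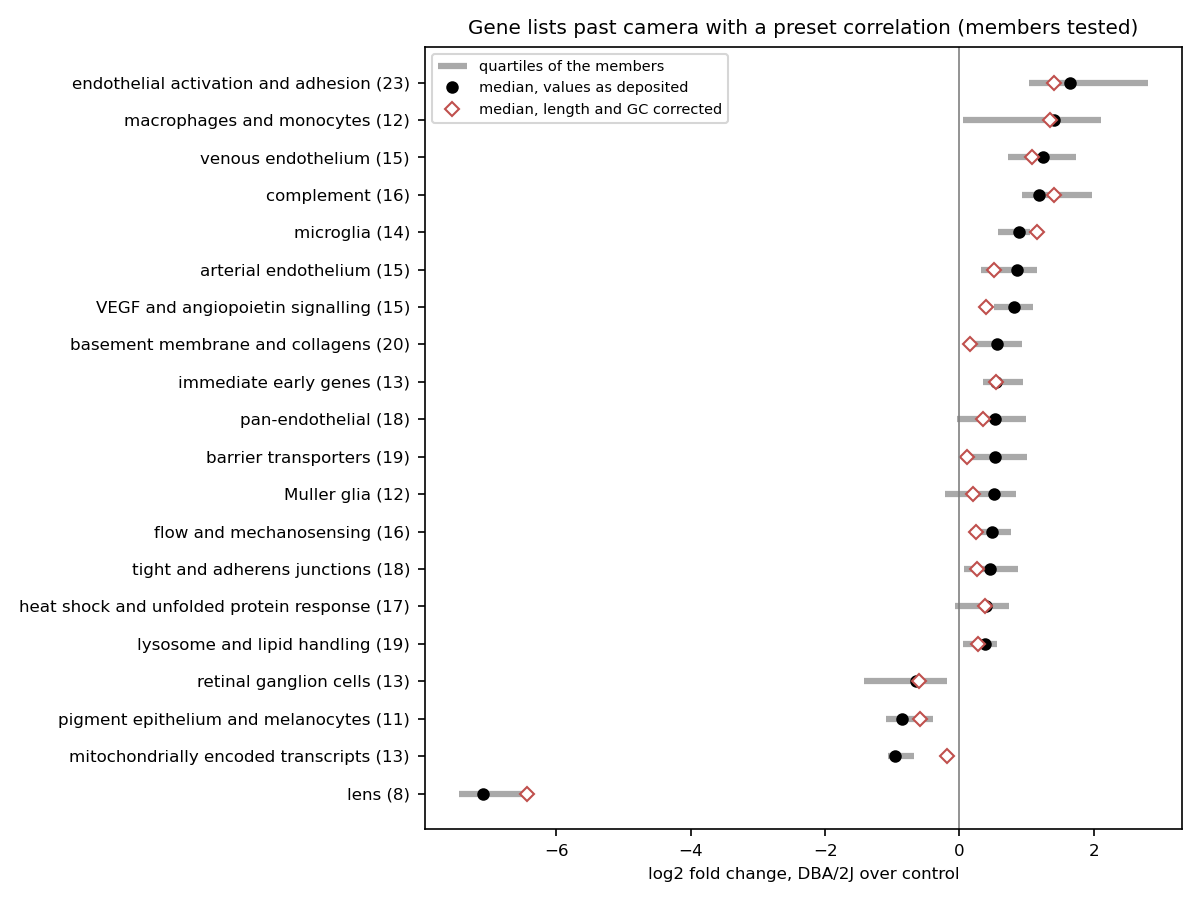
Each black point is the median log2 fold change (DBA/2J over control) of a list past camera with a preset correlation, the bar spans the quartiles of its members, and the open diamond is the median after removal of the length and GC trend. The lens list is at -7.09 and endothelial activation and adhesion at 1.65.

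Endothelial activation and adhesion genes, which bring leukocytes to the vessel wall, rose in 15 of 23 members and fell in none (18 adjusted over the list alone; median log2 fold change 1.65, adjusted p = 1.04e-07 by camera with a preset correlation; adjusted p = 0.76 with an estimated correlation). Selp, P-selectin (chromosome 1, 164115264 to 164150026), was at 0.676 ± 1.22 (SD, n = 5) in control, 3.65 estimated reads over the group, and at 401 ± 804 (SD, n = 9) in DBA/2J, with DBA/2J libraries between 4.7 and 2498 (sample 8; the others up to 520). Sele, E-selectin, was at 9.06 ± 8.42 and 588 ± 1137, with DBA/2J libraries between 7.3 and 3552.8 (sample 8; the others up to 762). Sample 8 thus carries most of both DBA/2J means. Ptgs2, cyclooxygenase 2, rose by 2.89 (SE 0.51, adjusted p = 0.00171, limma) and Il1r1, the interleukin 1 receptor, by 1.95 (SE 0.40, adjusted p = 0.00358). Vcam1 rose by 1.53 (SE 0.42, adjusted p = 0.0171), a call lost without control sample 3 (adjusted p = 0.0574), and after removal of the length trend its adjusted p was 0.0694. Icam1 had a log2 fold change of 1.32 and did not pass (adjusted p = 0.0573). It passed after removal of the length trend (1.251, adjusted p = 0.04925). The list's median was 1.41 after removal of the length trend (adjusted p = 1.24e-09), 1.33 with the pan-endothelial mean as a covariate and 0.928 with the leukocyte mean as a covariate, where 11 members were higher. Within the 9 DBA/2J libraries the list's mean log2 value lay between 7.15 (sample 4) and 10.12 (sample 8) and rose with library number (Pearson r = 0.847, exact permutation p = 0.00577, adjusted p = 0.0165 over 3 relations; Spearman rho = 0.833, exact permutation p = 0.00827, adjusted p = 0.0124). Without samples 1 and 9, r was 0.805. In the 5 controls, in order of library number, that mean was 6.967, 6.616, 6.601, 6.193 and 6.613, so it did not rise there.

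Venous endothelial markers rose in 7 of 15 members (median 1.25, adjusted p = 0.000374 by camera; adjusted p = 0.76 with an estimated correlation; 9 adjusted over the list alone). Selp, Il1r1, Lcn2, Vcam1, Icam1 and Ackr1 are also in the activation list, and Selp, Il1r1, Lcn2 and Vcam1 are among the 7. The venous list is thus not independent of the activation list. Aplnr, the apelin receptor, was at 2.78 ± 6.21 (SD, n = 5), all of it from control sample 3, and at 38.5 ± 38 (SD, n = 9). After removal of the length trend the list's median was 1.08 (adjusted p = 0.00344). Nr2f2, the transcription factor of venous identity, had a log2 fold change of 0.01 (adjusted p = 0.979) and Vwf one of 0.47 (adjusted p = 0.527).

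Barrier genes gave smaller differences, and their shares of higher members were not far from that of coding genes (3107 of 14889). Of 18 tight and adherens junction genes, 5 rose and none fell (median 0.461, adjusted p = 0.0254 by camera; adjusted p = 0.76 with an estimated correlation; 6 adjusted over the list alone). Tjp1, the scaffold ZO-1, rose by 0.88 (SE 0.20, adjusted p = 0.00682, limma) and Jam2, a junctional adhesion molecule, by 0.88 (SE 0.21, adjusted p = 0.00771). Neither passed after removal of the length trend (adjusted p = 0.169 and 0.137), where no junction gene was higher, 2 were lower and the list no longer passed (median 0.268, adjusted p = 0.343). Cldn5, the main claudin of retinal vessels, was at 8768 ± 2759 (SD, n = 5) and 7682 ± 5654 (SD, n = 9), with a log2 fold change of -0.45 that did not pass (adjusted p = 0.458). It was at -0.0058 (adjusted p = 0.993) after removal of the length trend. With the mean of the pan-endothelial list, which holds Cldn5 and Cdh5, as a covariate it passed at -1.04 (adjusted p = 0.000364). Cdh5, VE-cadherin, had a log2 fold change of 0.03 (adjusted p = 0.969; -0.55 with that covariate, adjusted p = 0.0464), Mfsd2a one of -0.20 (adjusted p = 0.705) and Plvap one of -0.33 (adjusted p = 0.347). Of 19 barrier transporters, 5 rose (median 0.532, adjusted p = 0.0259; adjusted p = 0.76 with an estimated correlation), among them Slc6a6, the taurine transporter, by 1.14 (SE 0.26, adjusted p = 0.00666; 0.101 after removal of the length trend). After that removal the transporter list did not pass (median 0.11, adjusted p = 0.712, 1 member higher and 1 lower). The junction call was lost without control sample 2, control sample 4 or DBA/2J sample 9 (adjusted p up to 0.0713), and the transporter call without those or DBA/2J sample 6 (up to 0.102). In DBA/2J samples 1 to 4 the junction mean log2 value was 9.566 to 9.917 and the transporter mean 9.332 to 9.869, near the controls (9.435 to 9.9 and 9.436 to 10.061). In samples 5 to 9 they were 10.066 to 10.686 and 10.055 to 10.963. Caveolae and transcytosis genes (5 of 13 higher, adjusted p = 0.146) and Wnt and Norrin signalling genes (4 of 19 higher, adjusted p = 0.159) did not pass as lists.

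Among growth factor receptors, Kdr, the main VEGF receptor of endothelium (chromosome 5, 75932827 to 75978458), rose by 1.68 (SE 0.20, adjusted p = 0.000129, limma), from 1766 ± 365 (SD, n = 5) to 5802 ± 1731 (SD, n = 9), with DBA/2J libraries between 3609 and 8618 and controls between 1464 and 2325. Of 15 VEGF and angiopoietin genes, 6 rose and 1 fell (median 0.81, adjusted p = 0.00198 by camera; adjusted p = 0.76 with an estimated correlation), Vegfb being the one that fell, by 0.72 (adjusted p = 0.00506; -0.16 after removal of the length trend, adjusted p = 0.361). After that removal the list's median was 0.402 (adjusted p = 0.0269). Pan-endothelial markers rose in 5 of 18 members (median 0.534, adjusted p = 0.0368; adjusted p = 0.796 with an estimated correlation), and arterial markers in 3 of 15 (median 0.857, adjusted p = 0.0259; adjusted p = 0.76 with an estimated correlation). Pecam1 rose by 1.04 (SE 0.32, adjusted p = 0.0293), a call lost without control sample 2, 3 or 4 or DBA/2J sample 6 (adjusted p up to 0.0905) and after removal of the length trend (adjusted p = 0.0943). Flow and mechanosensing genes rose in 4 of 16 members (median 0.487, adjusted p = 0.0259; adjusted p = 0.76 with an estimated correlation), led by Heg1, a junctional receptor, at 1.28 (SE 0.19, adjusted p = 0.000547). In the basement membrane list 1 of 20 members passed, Fn1 (median 0.564, adjusted p = 0.0381; adjusted p = 0.76 with an estimated correlation). Fn1, fibronectin, rose by 1.06 (SE 0.34, adjusted p = 0.0361), a call lost in 9 of the 14 leave-outs (adjusted p up to 0.0898) and after removal of the length trend (0.583, adjusted p = 0.197). The pan-endothelial call was lost in 7 of the 14 leave-outs (adjusted p up to 0.134), the arterial call without control sample 1 or 4 (up to 0.064), the flow call without control sample 4 or DBA/2J sample 9 (up to 0.0959) and the basement membrane call in 8 leave-outs (up to 0.129). After removal of the length trend the pan-endothelial (median 0.355, adjusted p = 0.0743), arterial (0.51, adjusted p = 0.0889), flow (0.241, adjusted p = 0.0889) and basement membrane lists (0.156, adjusted p = 0.921) did not pass. In DBA/2J samples 1 to 4 the mean log2 values of the pan-endothelial (9.58 to 10.149), flow (9.076 to 9.371) and basement membrane lists (8.064 to 8.659) did not exceed the highest control (10.507, 9.454 and 9.01). In samples 5 to 9 they were 10.471 to 11.727, 9.874 to 10.588 and 9.318 to 10.161. TGF-beta and BMP genes (7 of 21 higher, adjusted p = 0.0702) did not pass as a list.

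Complement genes rose in 8 of 16 members (12 adjusted over the list alone; median 1.19, adjusted p = 0.000322 by camera; adjusted p = 0.76 with an estimated correlation). Cfb, factor B of the alternative pathway, rose by 2.60 (SE 0.47, adjusted p = 0.00186, limma), C3 by 2.71 (SE 0.68, adjusted p = 0.0107) and C5ar1 by 4.20 (SE 0.82, adjusted p = 0.00282). The list's median was 1.41 after removal of the length trend (adjusted p = 1.22e-05), and 10 members were then higher. Macrophage and monocyte markers rose in 4 of 12 members (median 1.40, adjusted p = 0.0381; adjusted p = 0.76 with an estimated correlation), among them F13a1 by 2.40 (SE 0.49, adjusted p = 0.00354) and Ccr2 by 3.41 (SE 0.78, adjusted p = 0.00658). Chil3, at under 1 estimated read over the controls, is given no fold. That list's call was lost in 8 of the 14 leave-outs (adjusted p up to 0.125), and its median was 1.35 after removal of the length trend (adjusted p = 0.0269). Microglial markers gave 1 of 14 members past the threshold, Cx3cr1, a fractalkine receptor (2.14, SE 0.40, adjusted p = 0.00228), with a median of 0.885 and adjusted p = 0.0152 (0.76 with an estimated correlation; lost without control sample 4, adjusted p = 0.0515). With the length trend removed, 8 microglial members were higher and 1 lower (median 1.16, adjusted p = 0.000188). The rise was uneven between DBA/2J libraries. The microglial mean log2 value was 7.595 to 8.013 in DBA/2J samples 1 to 4 and 8.557 to 9.828 in samples 5 to 9 (controls 7.579 to 8.139). For macrophages and monocytes it was 5.125 to 6.345 and 6.835 to 8.375 (controls 5.144 to 6.027). This split was made after the values were seen. With the pan-endothelial mean as a covariate neither the microglial (median 0.414, adjusted p = 0.264) nor the macrophage list (median 0.786, adjusted p = 0.546) passed. Lymphocyte (1 of 12 higher, adjusted p = 0.152), neutrophil (1 of 7, adjusted p = 0.504), interferon response (4 of 27, adjusted p = 0.0905), MHC class I (1 of 14, adjusted p = 0.686), MHC class II (0 of 7, adjusted p = 0.492) and platelet lists (0 of 7 higher, 1 lower, adjusted p = 0.923) did not pass.

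Immediate early genes rose in 5 of 13 members (median 0.549, adjusted p = 0.00239 by camera; adjusted p = 0.76 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 2.12 (SE 0.22, adjusted p = 3.38e-05, limma), from 168 ± 59.6 (SD, n = 5) to 699 ± 132 (SD, n = 9), and by 2.15 after removal of the length trend, where the list's median was 0.543 (adjusted p = 0.000268). Heat shock and unfolded protein response genes rose in 8 of 17 members and fell in 1, Hspb1 (median 0.399, adjusted p = 0.0131; adjusted p = 0.76 with an estimated correlation; lost without control sample 4, adjusted p = 0.0531). Hspb1 fell by 0.89 (adjusted p = 0.046) and was at -0.147 after removal of the length trend (adjusted p = 0.643). Then 8 members were higher and none lower, and the list's median was 0.376 (adjusted p = 0.00318). Pdia4 rose by 0.88 (SE 0.16, adjusted p = 0.00223) and Xbp1 by 0.87 (SE 0.21, adjusted p = 0.00921). Mitochondrially encoded transcripts fell in 9 of 13 members (median -0.958, adjusted p = 2.16e-06; adjusted p = 0.76 with an estimated correlation). After removal of the length trend their median was -0.19 and the list did not pass (adjusted p = 0.264), with 1 member higher and none lower. Lysosome and lipid handling genes rose in 4 of 19 members (median 0.377, adjusted p = 0.0259; adjusted p = 0.76 with an estimated correlation; lost without control sample 4 or DBA/2J sample 9, adjusted p up to 0.17), and the list did not pass after removal of the length trend (median 0.278, adjusted p = 0.148). The lysosome list's mean log2 value was 10.666 to 10.875 in DBA/2J samples 1 to 4 and 11.144 to 11.589 in samples 5 to 9 (controls 10.255 to 10.959). Hypoxia and glycolysis (2 of 18 higher, 1 lower, adjusted p = 0.707) and cell cycle genes (2 of 16 higher, adjusted p = 0.134) did not pass.

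Retinal ganglion cell markers fell in 4 of 13 members and rose in none (6 adjusted over the list alone; median -0.646, adjusted p = 0.00511 by camera; adjusted p = 0.76 with an estimated correlation). Sncg, gamma-synuclein, fell by 1.42 (SE 0.29, adjusted p = 0.00356, limma) and Thy1 by 1.53 (SE 0.33, adjusted p = 0.00534). After removal of the length trend Sncg had a log2 fold change of -0.75 and missed the threshold (adjusted p = 0.139), Thy1 passed (adjusted p = 0.0154) and the list's median was -0.605 (adjusted p = 0.00344). With the pan-endothelial mean as a covariate the list did not pass (median -0.46, adjusted p = 0.168, 1 member higher and 4 lower). With the lens mean as a covariate the call was lost and the direction turned (median 0.323, adjusted p = 0.413; 0.193 with the length trend removed too). Muller glia markers rose in 5 of 12 members (median 0.514, adjusted p = 0.0485; adjusted p = 0.76 with an estimated correlation), a call lost in 7 of the 14 leave-outs (adjusted p up to 0.131) and after removal of the length trend (median 0.199, adjusted p = 0.426). Aqp4, the water channel of glial endfeet, rose by 1.71 (SE 0.25, adjusted p = 0.000509) and Kcnj10, their potassium channel, by 1.30 (SE 0.21, adjusted p = 0.000992). Pigment cell markers fell in 2 of 11 members, Gpnmb and Pmel, a melanosome matrix protein (-2.35, SE 0.45, adjusted p = 0.00255), with a median of -0.854 and adjusted p = 0.00198 (0.76 with an estimated correlation). Gpnmb differs between the strains by design, so this call is in part fixed in advance, and the list was not tested without it. After removal of the length trend the pigment list's median was -0.583 (adjusted p = 0.000188). Rods (1 higher, 1 lower of 13, adjusted p = 0.923), cones (0 of 9, adjusted p = 0.511), bipolar cells (3 of 9 higher, adjusted p = 0.38), amacrine cells (3 higher, 1 lower of 9, adjusted p = 0.686), horizontal cells (1 of 4 lower, adjusted p = 0.815) and astrocytes (1 higher, 1 lower of 7, adjusted p = 0.653) did not pass as lists. Pericytes (2 of 12 higher, adjusted p = 0.504), smooth muscle (1 higher, 1 lower of 10, adjusted p = 0.38), fibroblasts (0 of 11, adjusted p = 0.884), erythrocytes (0 of 6, adjusted p = 0.0762) and sex-linked genes (0 of 6, adjusted p = 0.152) did not pass either. Horizontal cell and platelet medians were above 0 (0.113 and 0.208) while camera ranked both lists lower.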

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

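The tests of library series, of retinal crystallins and the list of lens fibre structural genes were chosen only after the results were seen, as were the length, lens, endothelial and leukocyte corrections.

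In 15 of 360 groups of values 1 library stood far from the others, where chance gives about 1 in 20. In control sample 3 these were Adgra2 at 286.1 (others up to 192.6), Stat2 at 178.3 (others from 271.7), Aplnr at 13.9 and Chil3 at 0.4 (others 0), and the mean log2 values of MHC class I presentation (10.29) and venous endothelium (8.2). In control sample 4 they were Hspa5 at 921.7 (others from 1673.4) and the lysosome and lipid handling mean at 10.26. Rp1 was at 11617.2 in control sample 5 (others up to 6324). In DBA/2J, Gapdh was at 17158.3 in sample 3, Dkk3 at 99578.5 in sample 5, Tsix at 447.7 in sample 7 and S100b at 1545.1 in sample 9. DBA/2J sample 9 also had the highest means of the cell cycle list (6.47) and of the lymphocyte list (7.12, others up to 4.77).

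Longer transcripts were higher in DBA/2J. A mixture of cell types that differ in transcript length is argued against by a slope of 0.313 per doubling of length (SE 0.0968) within 4 retinal neuron lists, each centred on its own median. A length-dependent step in library making that differed between the library series cannot be told apart from strain: the lowest DBA/2J slope exceeded the highest control slope by 0.051, and library numbers part the groups the same way. A biological difference between the strains stays open and untested.

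Lens transcripts were higher in control libraries. The lens fibre structural genes were also lower in DBA/2J, 8 of 8, with a median log2 fold change of -5.93 (-6.39 to -5.18 without any one library). That list was chosen after the results were seen, and its members Mip, Grifin and Gja3 are among the largest falls. It therefore cannot decide whether retinal cells made the crystallins. The values show only that the difference extended to lens genes other than crystallins. Lens tissue carried into the dissections stays open as a candidate source: within the 9 DBA/2J libraries the lens list and the fibre genes moved together (Pearson r = 0.984). Cryaa, the most abundant, stood at 775000 ± 269700 (SD, n = 5) in control. Why the carry-over would follow the strain was not tested, and lens differences between the strains remain possible.

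The activation and adhesion list was higher in DBA/2J. More endothelial RNA, the length trend and leukocytes carried with blood are each argued against as the whole cause. The list's median stayed at 1.33 with the pan-endothelial mean as a covariate, at 1.41 after the length and GC correction and at 0.928 with the leukocyte mean as a covariate, and without any one library at no less than 1.04, 1.27 and 0.92. Library order stays open, since within the 9 DBA/2J libraries the list rose with library number (r = 0.847, exact permutation p = 0.00577), although in the 5 controls it did not (6.967 in the first library and 6.613 in the last). Raised intraocular pressure in DBA/2J may account for the rise, as may Gpnmb itself or the library series, none of which these libraries separate.

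For the gene counts chance could be excluded: 1 of 100 splits of the 14 libraries, the real one, gave 3518 or more higher genes (highest other 1250), and 1 of 100 gave 2101 or more lower genes (highest other 433). For the list counts chance could not be excluded: 21 of 100 splits gave 16 or more higher lists (highest other 29) and 57 of 100 gave 4 or more lower lists (highest other 28).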

How the results depend on the processing

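The length and GC correction, the lens, pan-endothelial and leukocyte covariates, their combinations, the voom weights and the omission of the 2 shallowest libraries were added after seeing the data. Of 136 named genes besides Gpnmb, 7 kept direction and side of the threshold in every alternative that tested them, as did 12 of 42 lists, and 87 of 120 called genes and 9 of 20 called lists passed without any one library. The stricter filter left some of these genes and lists untested. In 52 cases a gene changed sign where neither setting passed. The cause was not tested unless stated.

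Without any one library, higher genes numbered 2283 (control sample 3) to 3974 (control sample 1), lower genes 1247 to 2341, higher lists 5 to 18 and lower lists 4 to 5, and the Gpnmb difference ran from -3.771 to -3.364. Controls 1 to 3 alone gave 2334 higher and 1373 lower genes and 5 higher lists, and controls 4 and 5 alone 1673 higher and 773 lower genes and 16 higher lists. The replicate block gave 1408 higher and 1057 lower genes and 5 higher lists, and -0.152 for the pan-endothelial list. No control has the numbers 6 to 9, so DBA/2J samples 6 to 9 did not enter that contrast. Their pan-endothelial means were the highest (10.813 to 11.727, controls 9.678 to 10.507). The block therefore does not test the contrast over all libraries. The numbers did not pair the samples: same-numbered correlations ran from -0.0824 to 0.0154, and 0 of 5 controls matched their own number best. Voom weights gave 5213 higher and 1338 lower genes, with the median of all genes at 0.23 against 0.047. That fit also scaled each library to its own total in place of the deposited factors, so the weights alone were not tested. Quantile normalization gave 2740 higher and 2868 lower genes. The Xist covariate gave 5 higher lists, the stricter filter 2, and camera with an estimated correlation 0 higher and 0 lower (1 list at an unadjusted p under 0.05, 3 past fry). The length and GC correction gave 1859 higher genes, 1359 of them also higher as deposited, and 8 higher lists.

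The lens covariate gave 2 higher genes (Ptges3-ps and Atf3, the first named after its value was seen) and 10 lower, all called without it too. It gave 4 higher lists, also called without it, and 1 lower list that was not (0 of the 4 lower lists were kept), and the Gpnmb difference at -2.797 (SE 0.579 against 0.38). The lens mean correlated with group at r = 0.78 and standard errors grew by a median factor of 1.63, so this fit has little power. With the length correction as well it gave 6 higher genes (5 also called as deposited), 23 lower genes (22), 4 higher lists (4) and 3 lower lists (1). The Muller glia covariate gave 623 higher and 1133 lower genes, 2 higher lists and 8 lower. The leukocyte covariate gave 2 higher lists, and the pan-endothelial covariate 5 with or without the length correction.

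Directions turned as follows, as log2 fold changes (medians for lists, where the direction is camera's and the median can keep its sign). A list that gives the covariate, and its members, are in part measured against themselves, and those are given first. With the lens covariate these were the lens list 0.385, Cryaa 0.43, Cryba1 0.62, Cryba4 0.34, Crybb2 0.53 and Crygs 0.27, and with the length correction too the lens list 0.267, Cryaa 0.29, Cryba1 0.25, Cryba4 0.38, Crybb2 0.59 and Crygs 0.17. The pan-endothelial list was at -0.0369 with its own mean and 0.0372 with the length correction too, Cdh5 at -0.55 and -0.83, Muller glia at 0.105 with its own mean, and macrophages and monocytes at 0.405 with the leukocyte mean. Other turns with the lens covariate were Nefm 0.041, Sema3g -0.60, arterial endothelium -0.0227 and retinal ganglion cells 0.323. With the length correction too they were Cryba2 0.00297, Calb2 0.17, Jam2 -0.12, Sema3g -0.62, Sncg 0.19, mt-Co3 0.14, arterial endothelium -0.296, barrier transporters -0.0891, basement membrane 0.0472, mitochondrial transcripts 0.132, pan-endothelial -0.197, retinal ganglion cells 0.193, rods -0.249 and junctions 0.0699. With the length correction and pan-endothelial covariate they were barrier transporters 0.0998, basement membrane 0.0422 and junctions 0.138. With the Muller glia covariate they were MHC class I -0.523, Wnt and Norrin -0.41, barrier transporters -0.283, basement membrane -0.0931, fibroblasts -0.611, flow -0.134, lysosome -0.0531, microglia -0.0369, pan-endothelial -0.479 and junctions -0.124. With the leukocyte covariate they were MHC class I -0.339 and pan-endothelial -0.142. Most turns did not pass in the turned direction. By camera, MHC class I (adjusted p = 0.0139), fibroblasts (0.0167) and Wnt and Norrin (0.028) passed with the Muller glia covariate. MHC class I passed with the leukocyte covariate (0.0128), and rods with the lens covariate and length correction (0.0464). By limma, Cdh5 passed with the pan-endothelial covariate (0.0464, and 0.00667 with the length correction too). Depth limits genes of a few reads: 1 read was worth 0.546 to 1.84 across libraries.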

Other observations

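The tests of ganglion cell markers against a damage gradient, against rods and against library number were chosen only after the result was seen, and the bounds of the length test were set before its value was computed but with the uncorrected correlation known.

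Genes linked to retinal stress and reactive glia were also higher in DBA/2J veins, in a list assembled after the values were seen and so not independent evidence. Of its 16 members 13 were higher and 1, Hspb1, lower, with a median log2 fold change of 1.69 (1.32, with 11 higher and 1 lower, after the length and GC correction). Vim, at -0.704 (adjusted p = 0.0746, limma), and Nes, at 0.16 (adjusted p = 0.8), did not pass. After the correction Vim was the lower member, at -0.927 (adjusted p = 0.0246). Stat3, a transcription factor of cytokine signalling, stood at 374 ± 42.8 (SD, n = 5) in control and 1109 ± 273 (SD, n = 9) in DBA/2J, with no overlap between 351 to 450 and 682 to 1343. Serpina3n, an acute-phase protease inhibitor, rose by 2.58 (SE 0.52, adjusted p = 0.00322, limma), Osmr, the oncostatin M receptor, by 1.84 (SE 0.33, adjusted p = 0.00171), Edn2, endothelin 2, by 1.96 (SE 0.48, adjusted p = 0.00945) and Lif by 2.71 (SE 0.66, adjusted p = 0.00956). Gfap was at 4612 ± 2392 and 13990 ± 9222, a call lost without control sample 4 (adjusted p = 0.055).

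Across the 9 DBA/2J libraries ganglion cell markers were lower where the activation and adhesion mean was higher (Pearson r = -0.715, exact permutation p = 0.0256, adjusted p = 0.0366 over 9 relations; Spearman rho = -0.783, exact permutation p = 0.0172, adjusted p = 0.031). Without the 2 samples farthest from the median, DBA/2J samples 8 and 4, r was -0.892. Both measures also followed library number: activation rose with it (r = 0.847) and ganglion cell markers fell (r = -0.774, exact permutation p = 0.011, adjusted p = 0.0165 over 3 relations; rho = -0.917, exact permutation p = 0.00131, adjusted p = 0.00394; -0.709 without samples 1 and 9). With a linear trend on library number removed from both, r was -0.175 (exact permutation p = 0.618), so library order may account for the relation. A hypothesis that damage varies between these mice and moves both measures stays untested, since the r of -0.715 is the observation that raised it.

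A technical gradient with transcript length is argued against as the cause of that relation, since r was -0.747 after the length and GC correction, although the length slope itself followed activation (r = -0.807, exact permutation p = 0.00405, adjusted p = 0.00912; rho = -0.817, exact permutation p = 0.0108, adjusted p = 0.0242; -0.584 without samples 8 and 4). Less neural retina in libraries with more vessel cannot be told apart: rod markers fell with activation too (r = -0.729, exact permutation p = 0.0284, adjusted p = 0.0366; rho = -0.667, exact permutation p = 0.0589, adjusted p = 0.0757; -0.561 without those 2), and the ganglion cell slope minus the rod slope was -0.244 (SE 0.282). Pan-endothelial markers rose with activation (r = 0.758, exact permutation p = 0.0229, adjusted p = 0.0366; rho = 0.717, exact permutation p = 0.0369, adjusted p = 0.0553, which does not pass; 0.866 without those 2), as did macrophage and monocyte markers (r = 0.933, exact permutation p = 0.000628, adjusted p = 0.00283; rho = 0.9, exact permutation p = 0.00203, adjusted p = 0.00913; 0.897), complement (r = 0.95, exact permutation p = 0.000295, adjusted p = 0.00265; rho = 0.9, exact permutation p = 0.00203, adjusted p = 0.00913; 0.942) and microglia (r = 0.887, exact permutation p = 0.00316, adjusted p = 0.00912; rho = 0.833, exact permutation p = 0.00827, adjusted p = 0.0242; 0.853). Muller glia (r = 0.611, exact permutation p = 0.0866; rho = 0.55, exact permutation p = 0.133; 0.762) and the lens list (r = -0.202, exact permutation p = 0.59; rho = -0.2, exact permutation p = 0.613; -0.719) did not pass.

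Outside the named genes, the processed pseudogene Pgam1-ps2, chosen after its values were seen, was at 0 to 174 in control and 223 to 3080 in DBA/2J, while its parent Pgam1 was at 8070 and 8190 (adjusted p = 0.909).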
